A study of Mus musculus with 6 samples.

How the data were processed

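The samples were macrophages taken from the epididymal fat of male C57BL/6J mice with an antibody to the pan-macrophage antigen encoded by Adgre1 and magnetic selection, after collagenase digestion of the fat and isolation of the stromal vascular fraction. Mice were 6 weeks old at the start and received normal chow (NCD) or a diet with 60% fat (HFD) for 16 weeks, until 22 weeks of age. Each diet had 3 samples, whose titles call them biological replicates; each NCD sample pooled 20 mice and each HFD sample 10 mice. From each pool, 100 ng of total RNA was labelled for 1 Affymetrix array of transcript clusters, the probe sets that stand for a gene or transcript. The arrays are written here as NCD1 to NCD3 and HFD1 to HFD3. Pools, and not mice, were the unit of replication, so the spread between single mice was not measured.

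The deposited table holds log2 expression per transcript cluster, 1 column per sample, as the authors made it. The submitters' processing notes name Affymetrix Expression Console 1.4.1.46, RMA and Transcriptome Analysis Console 3.1.0.5; the step done by each, the options, the library files and the genome build were not given in the sources used here. The column medians over all probe sets were 6.03, 6.02 and 5.95 for NCD1 to NCD3 and 5.95, 5.95 and 5.96 for HFD1 to HFD3, so the columns had close but not identical levels. On arrays there is no read depth, and the number of arrays limits the precision: the median standard error of the log2 difference between diets was 0.118.

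The table had 6732 control probe sets, which were left out, and 65956 transcript clusters. Of the clusters, 30604 carried 1 gene symbol, 2146 several and 33206 none. The array's gene annotation is old: 22815 of the clusters with 1 symbol matched a current gene by Entrez identifier, and 827 of these received an updated symbol. Genes are named by those symbols, and chromosome positions were not used here. The tests used the clusters with 1 symbol and kept 1 cluster per gene, the one with the highest mean over the 6 arrays, which gave 30142 genes. For 355 genes there were several clusters, and 0 of these genes had clusters called in opposite directions. Dim genes were kept. The 23 antigenomic background probe sets gave a background level of 6.23 log2, the mean over arrays of their 95th percentile; 14395 genes (47.8%) had a mean below it, and 263 of the genes called were among them.

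The 2 diets were compared with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend; 2.64 prior degrees of freedom) in R 4.3.3, with data read by version 1.17.8 of data.table. P values were two-sided and adjusted with the Benjamini-Hochberg method over all 30142 genes, and a gene was called at an adjusted p below 0.05. Changes are log2 HFD minus NCD with the moderated standard error, and array groups are given as mean and SD. Gene lists were tested with limma's camera with a preset correlation between genes of 0.01 and a variance trend, adjusted over the 35 lists with at least 5 measured genes. They were tested again with camera and a correlation estimated from the arrays, and with fry, limma's rotation test. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. On simulated data of the same size (10 runs of 30142 genes, 200 of them changed, 3 arrays against 3), the gene test recovered 80.6% of 2-fold and 97.4% of 4-fold changes, with 0 wrong signs and a mean of 10.1 false calls. The simulated genes were independent and had the same variance in both diets. The real arrays had correlated genes and a wider spread in NCD, so these rates need not hold for them.

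The design, the alternatives, the 36 gene lists and the rule for named genes were fixed before the data were examined. The program lists held macrophage identity, lipid-associated macrophage genes, resident tissue macrophage genes, interleukin-4 response genes, pro-inflammatory cytokines and enzymes, chemokines and chemokine receptors, interferon-stimulated genes, MHC class II presentation, lysosome, lipid uptake, storage and efflux, cholesterol biosynthesis, glycolysis, oxidative phosphorylation, fatty acid oxidation, cell cycle, hypoxia response, immediate early and heat shock genes, unfolded protein and integrated stress response, oxidative stress and iron handling, matrix remodelling enzymes and inhibitors, and macrophage transcription regulators. The cell type lists held markers of monocytes, large peritoneal macrophages, dendritic cells, eosinophils, neutrophils, mast cells, T cells, natural killer cells, B and plasma cells, adipocytes, fibroblasts and adipose progenitors, mesothelium, endothelium, erythroid cells and epididymal epithelium. A list of smooth muscle and pericyte markers was added after the values were seen; its set tests stand outside the adjustment over lists. The 36 lists held 661 distinct genes, of which 596 were measured; the other 65 were not analysed here.

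Named genes were the 12 largest rises and the 12 largest falls among called genes whose 3 arrays of one diet all lay beyond the 3 of the other. Gene models, clones, small RNAs, immunoglobulin and T cell receptor segments, and olfactory and vomeronasal receptors were left out of these. Also named were the 4 members of each list with the smallest adjusted p, and always Adgre1, Itgax, Trem2, Mrc1, Tnf and Il1b. Outside this rule, Igf1, Rxra, Tpi1, Pfkl, Pfkfb3, Txnrd1, Slc40a1, Timp3, Cebpa, Id3, Gas6, Lyve1, Jun, Il6, Arg1, Cdh5, Efemp1, Dcn, Hdc and members of gene families were named after their values were seen.

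The alternatives were quantile normalization of the columns again, median centring, filters that dropped genes below the median level or in the lowest 25%, averaging of the probe sets of a gene, the variance model without a trend or with robust shrinkage, array quality weights, and a per-gene linear model F test without variance shrinkage. The replicate number of the titles as a block, leaving out each array in turn, all transcript clusters with or without a symbol, and lists without shared genes were also run. A filter at the antigenomic background level and a fit with a score of endothelial markers as a covariate, the mean deviation of those markers per array, were added after the data were seen. Gene families, groups of symbols with a common stem, were screened with camera after the data were seen.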

Results

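The series concerned how the transcriptome of adipose tissue macrophages changes in diet-induced obesity. Array expression of macrophages from epididymal fat, selected by an antibody to the antigen that Adgre1 encodes, was compared between mice on a high-fat diet (HFD, 3 pools) and on normal chow (NCD, 3 pools). All changes below are log2 HFD minus NCD with their standard error from limma, with 3 arrays per diet.

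Cells from HFD mice had higher levels of genes of lysosomes, of lipid-associated macrophages, of cholesterol synthesis and of the cell cycle. Trem2, a lipid-sensing receptor of lipid-associated macrophages, rose 7.19-fold (2.85 ± 0.17, adjusted p = 0.00143), and Ctsk, a lysosomal protease that degrades collagen, rose 14.7-fold (3.88 ± 0.18, adjusted p = 0.000717). Genes of resident tissue macrophages were lower: the C-type lectin gene Cd209f fell 14.8-fold (−3.88 ± 0.26, adjusted p = 0.00207) and Cd163, the scavenger receptor for haemoglobin, fell 7.82-fold (−2.97 ± 0.25, adjusted p = 0.00350). Lower as well were the interleukin-4 response gene Retnla, which fell 7.74-fold (−2.95 ± 0.26, adjusted p = 0.00392), immediate early genes, mesothelial genes, and 9 of 16 smooth muscle genes on a list added after the values were seen. The list calls behind these groups used a preset correlation between genes, and 0 of 35 lists were called with an estimated correlation (smallest adjusted p = 0.316). The gene of the selection marker itself, Adgre1, had a mean of 15.69 ± 0.56 (SD) in NCD and 16.60 ± 0.09 in HFD arrays and was not called (0.91 ± 0.27, adjusted p = 0.0924). Its change ran from 0.59 to 1.11 over fits without 1 array, was called without NCD1 and without NCD3, and was 0.44 with a covariate of endothelial markers.

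Of 30142 genes tested, 2359 (7.83%) passed an adjusted p of 0.05: 1494 were higher after HFD, 594 of them by at least 2-fold, and 865 were lower, 417 of them by at least 2-fold. The median change over all genes was 0.01, and the higher genes were 63.3% of those called (58.8% at 2-fold). This share was 50.9% without NCD1 (40.3% at 2-fold), 52.1% without NCD3, 54.8% with array weights (43.9% at 2-fold) and 46.1% with the endothelial covariate, and 66.7% to 72.8% without each of the other arrays. Median centring moved that median to 0.10 and called 2573 genes higher and 693 lower, with 0 sign changes among the 2181 genes called both ways. The count moved with single arrays: it was 4713 without NCD1, 474 without NCD2, 1790 without NCD3, 1018 without HFD1, 442 without HFD2 and 456 without HFD3. Fits without 1 array also had fewer residual degrees of freedom, so a call lost in them need not mean a smaller change. With the score of endothelial markers as a covariate 310 genes were called higher and 363 lower, 502 of them shared with the 2359. Across all 65956 transcript clusters, the HFD arrays correlated with one another at r between 0.9947 and 0.9952. The NCD arrays did so at 0.985 to 0.993, and arrays of different diets at 0.976 to 0.988.

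The 12 largest rises lay between 3.29 and 4.05. Beside Ctsk they held Myh15 (a myosin heavy chain, 4.05 ± 0.19, 16.6-fold, adjusted p = 0.000717), the protocadherin Pcdh7 (3.90 ± 0.18, 14.9-fold) and Zranb3, a DNA translocase of stalled replication forks (3.88, 14.7-fold, adjusted p = 0.000619). The others were Plxdc1 (3.72), the retinoid and steroid dehydrogenase gene Dhrs9 (3.69), the adhesion molecule Cadm1 (3.53), the kinase Cdk18 (3.52), the tetraspanin-like Tm4sf19 (3.50), the inhibitory receptor Cd72 (3.50), the atypical cadherin Fat3 (3.49) and Hpgds, the haematopoietic prostaglandin D synthase (3.29). All 12 kept their call without each array in turn and with the endothelial covariate. The NCD mean of Fat3 (5.67) lay below the background level of 6.23, so the size of its rise is uncertain.

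The 12 largest falls lay between −4.91 and −3.54. One set held genes of contractile and vessel wall cells: Ccn1, a matricellular protein (−4.91, 30.1-fold lower), Myl9 (myosin light chain, −4.76, 27.1-fold lower), Acta2 (smooth muscle actin, −4.66, 25.3-fold lower), Myh11 (smooth muscle myosin, −4.53, 23.1-fold lower), Rgs4 (−4.40), Tagln (transgelin, −4.31) and Fhl5 (−3.54). These 7 genes lost their call without NCD2, without HFD2 and without HFD3, and Tagln also without NCD3. With the endothelial covariate the values were −2.94 for Ccn1, −3.13 for Myl9, −3.08 for Acta2, −3.09 for Myh11, −2.73 for Rgs4, −2.31 for Tagln (adjusted p = 0.0713) and −2.14 for Fhl5 (adjusted p = 0.0527). The other set held macrophage genes: the lectins Cd209g (−4.30, 19.6-fold lower, adjusted p = 0.00143), Cd209d (−4.15, 17.7-fold lower) and Cd209f, and the eotaxin gene Ccl24 (−4.11, 17.2-fold lower), all 4 of which kept their call without each array and with the covariate. Hsp25-ps1 (−3.75, adjusted p = 0.0332), a pseudogene of a small heat shock protein that was not told apart from its parent gene here, was called with all 6 arrays and without NCD1, and not without any other array.

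**Figure D1:**
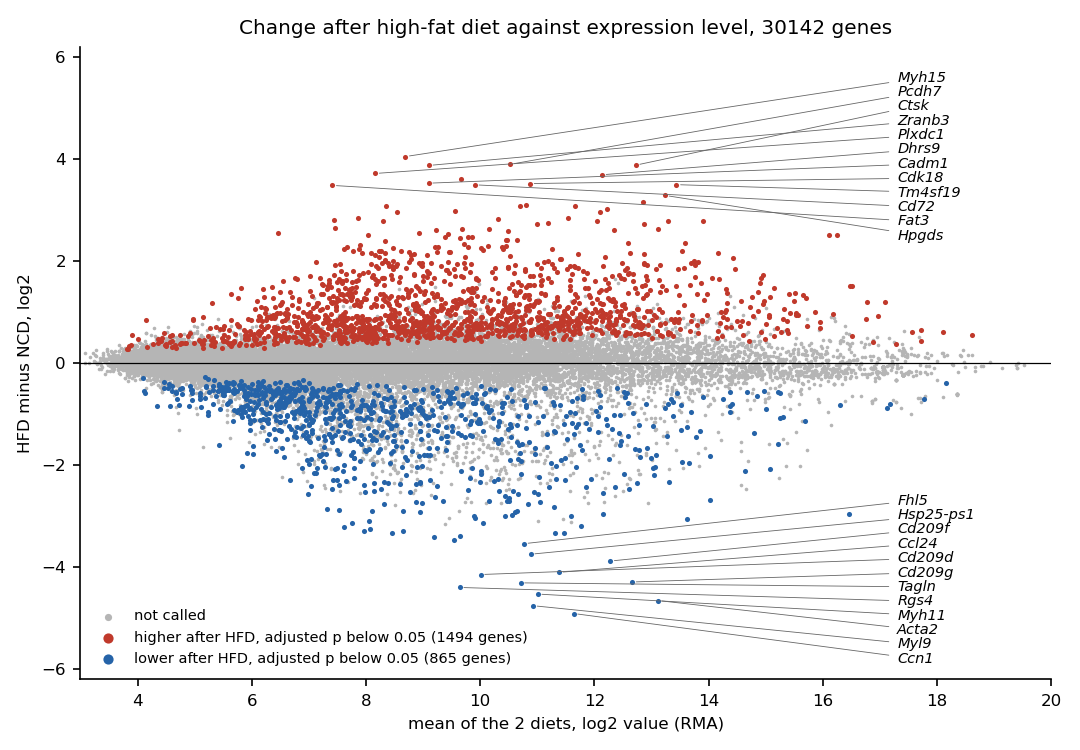
Log2 change (HFD minus NCD, vertical axis) of each of 30142 genes against its mean log2 level over the 6 arrays (horizontal axis), each point 1 gene. Coloured points are the 1494 genes called higher and the 865 called lower at an adjusted p of 0.05, and the genes with the largest changes are named.

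Lipid-associated macrophage genes, the program of macrophages that take up lipid in obese fat, were largely higher. Of 18 measured genes 14 rose, 0 fell and 4 were not called (14 higher and 1 lower adjusted over the list alone), with a median of 1.19 (camera adjusted p = 9.31e-12; adjusted p = 0.316 with an estimated correlation). Beside Trem2, the glycoprotein gene Gpnmb rose by 2.51 ± 0.15 (5.72-fold), the proton pump subunit Atp6v0d2 by 2.52 ± 0.24 and the protease Ctsl by 1.52 ± 0.15, all called without each array in turn. Of the 14 genes, 9 were called without HFD2 and 8 without HFD3, 1 other gene was called lower without NCD1, and with the endothelial covariate the median was 0.92 with 7 called. The integrin gene Itgax (CD11c), a marker of macrophages that accumulate in obese fat, rose 3.80-fold (1.93, adjusted p = 0.00938). The Itgax call was lost without NCD2 or HFD3, at changes of 1.73 to 2.19 over all fits without 1 array, and with the covariate (1.51, 2.84-fold, adjusted p = 0.0535). Mrc1, the mannose receptor, was at −0.09 (adjusted p = 0.833).

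Lysosome genes rose together: 22 of 34 were higher, 0 were lower and 12 were not called (27 higher and 1 lower adjusted over the list alone), with a median of 0.79 (camera adjusted p = 2.45e-16; adjusted p = 0.319 with an estimated correlation). The 4 with the smallest adjusted p were Ctsk, Gpnmb, Atp6v0d2 and Ctsl. The number of lysosome genes called was 12 without NCD2, 13 without HFD1, 10 without HFD2 and 8 without HFD3, and with the covariate it was 9, at a median of 0.58. In the list of lipid uptake, storage and efflux, 8 of 26 genes rose, 1 fell and 17 were not called (9 higher and 3 lower adjusted over the list alone). Among them were the cholesterol exporter Abcg1 (1.63 ± 0.16), the acid lipase Lipa (1.19 ± 0.13), the lipoprotein lipase Lpl (1.52 ± 0.17) and the cholesteryl ester hydrolase Nceh1 (2.14 ± 0.26, not called without HFD2 or HFD3), while the nuclear receptor Rxra fell by 0.52. The number higher was 5 without NCD2 and 3 without HFD2 or HFD3, 8 rose and 5 fell without NCD1, and 0 fell without NCD2, NCD3, HFD2 or HFD3. This list was not called as a whole (median 0.19, camera adjusted p = 0.0875), and was called without NCD2 (adjusted p = 0.0262) and without NCD3 (median 0.11, adjusted p = 0.0356). Its median was 0.04 without NCD1, 0.12 without HFD2 and 0.09 without HFD3.

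Genes of cholesterol biosynthesis were higher: 12 of 18 rose, 0 fell and 6 were not called (15 higher and 0 lower adjusted over the list alone). Their median was 0.79 over the list (camera adjusted p = 1.40e-11; adjusted p = 0.316 with an estimated correlation). Squalene epoxidase, Sqle, rose 2.86-fold (1.52 ± 0.12), Hsd17b7 by 1.31 ± 0.11, Fdps by 1.19 ± 0.11 and Nsdhl by 0.92 ± 0.10, and these 4 kept their call without each array in turn. The number called was 5 without NCD2, 4 without HFD2, 4 without HFD3 and 4 with the covariate.

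Oxidative phosphorylation had 3 of 38 genes higher, the ATP synthase subunit Atp5g1 (0.60 ± 0.11) and the succinate dehydrogenase subunits Sdhd (0.73 ± 0.14) and Sdhc (0.75 ± 0.15), 0 lower and 35 not called (4 and 0 adjusted over the list alone). Their median was 0.24 over the list (camera adjusted p = 2.12e-05; adjusted p = 0.515 with an estimated correlation). Of these 3, 0 were called without NCD2, HFD1, HFD2 or HFD3. Fatty acid oxidation had 3 of 21 genes higher, Hadha (0.90 ± 0.12), Hadhb (0.71 ± 0.15) and Acot2 (0.54 ± 0.12), 0 lower and 18 not called (7 and 0 adjusted over the list alone). Their median was 0.14 over the list (camera adjusted p = 0.0167; adjusted p = 0.594 with an estimated correlation). Of these, 1 was called without NCD2 or HFD1 and 0 without HFD2 or HFD3. That list call ended without NCD1 (adjusted p = 0.439), with median centring (0.0536), with genes below the median level dropped (0.0658) and with array weights (0.0526). The fatty acid oxidation median was 0.06 without NCD1 (6 higher, 1 lower), 0.28 without NCD3, 0.22 without HFD1, 0.06 without HFD3 and 0.33 with the endothelial covariate. In glycolysis the hexokinase Hk3 (1.67 ± 0.20), Pkm, Pgk1, Pgam1 and Tpi1 rose, Pfkl and Pfkfb3 fell and 10 of 17 were not called (8 higher and 2 lower adjusted over the list alone). Their median was 0.18 over the list (camera adjusted p = 0.0736; adjusted p = 0.594 with an estimated correlation). Hk3 alone of the glycolysis genes was called without NCD2, HFD1, HFD2 or HFD3, while 7 were higher and 3 lower without NCD1 and 2 and 2 without NCD3. The glycolysis median was 0.42 without NCD1 and 0.06 without HFD2.

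Cell cycle genes were the list with the smallest camera p at the preset correlation, but not with an estimated correlation or with fry: 29 of 31 rose, 0 fell and 2 were not called (31 higher and 0 lower adjusted over the list alone), with a median of 1.72 (camera adjusted p = 1.79e-23; adjusted p = 0.319 with an estimated correlation). The survivin gene Birc5 rose by 1.15 ± 0.12, the replication helicase subunit Mcm3 by 1.23 ± 0.14, the spindle factor Tpx2 by 2.47 ± 0.29 (5.55-fold) and the ribonucleotide reductase subunit Rrm2 by 2.03 ± 0.25, the last not called without NCD2. The mean deviation of the list was −0.51, −0.90 and −1.19 on NCD1 to NCD3 and 0.66, 0.65 and 1.29 on HFD1 to HFD3. The number of genes called was 5 without NCD2, 15 without HFD2 and 17 without HFD3. With the endothelial covariate 7 were called and the median was 1.34.

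**Figure D2:**
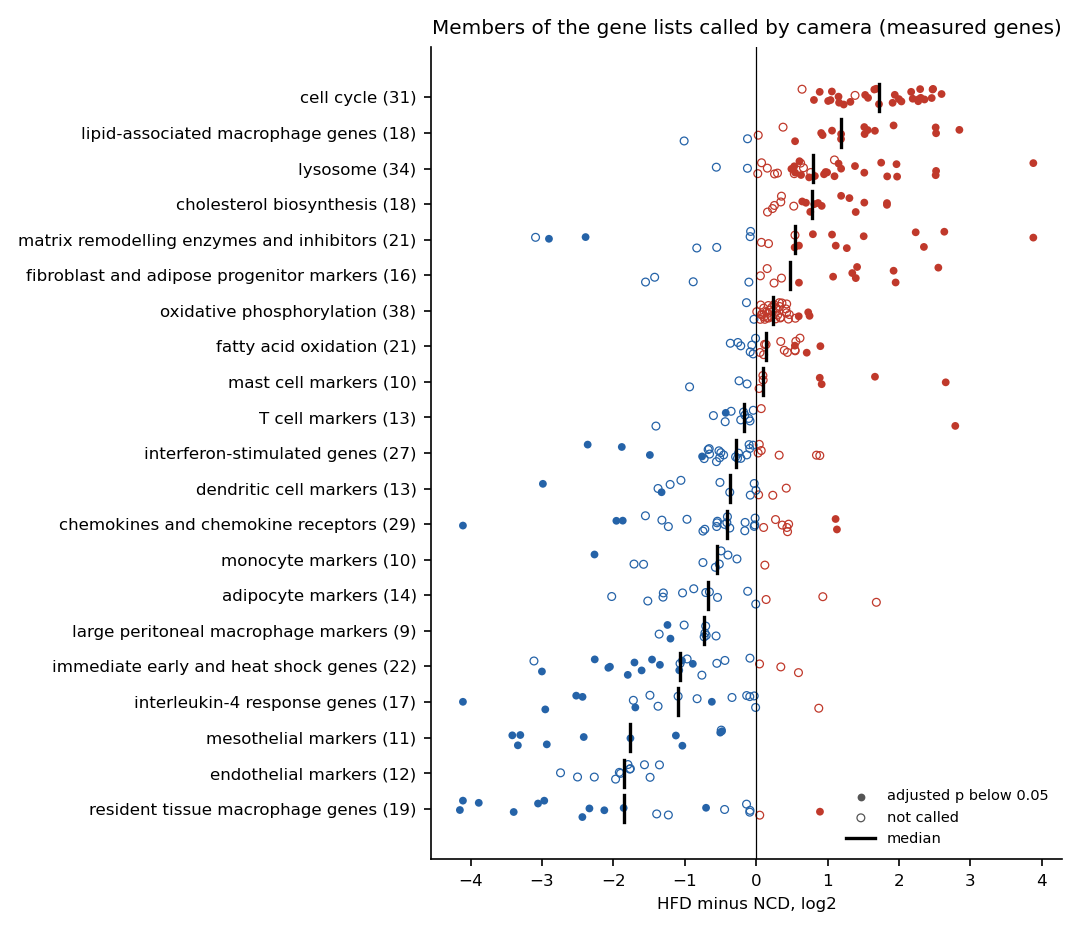
Log2 change (HFD minus NCD, horizontal axis) of each measured gene of the program and cell type lists called by camera at the preset correlation. Each list has 1 row with its number of measured genes, and lists not called are not shown. Filled points are genes called at an adjusted p of 0.05, open points are genes not called, and the black bar is the list's median (1.72 for cell cycle, −1.85 for resident tissue macrophage genes).

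Genes of resident tissue macrophages, those of the long-lived perivascular population of the tissue, were lower. Of 19 measured, 11 fell, 1 rose (Igf1, 0.89 ± 0.14) and 7 were not called (13 lower and 1 higher adjusted over the list alone). Their median was −1.85 over the list (camera adjusted p = 4.11e-11; adjusted p = 0.319 with an estimated correlation). Beside Cd209f, Cd209d and Cd163, Cd209b fell 10.5-fold (−3.40 ± 0.26), Lyve1, the hyaluronan receptor, fell by 3.05 and Gas6, a ligand of the receptor Mertk, by 1.85. Igf1 was not called without NCD2, HFD1, HFD2 or HFD3. The number of genes called lower was 10 to 12 without each array in turn, and it was 10 at a median of −2.28 with the endothelial covariate. The Cd209 genes are close copies, and shared probe sequence between them was not tested.

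Interleukin-4 response genes, the alternatively activated program, were lower too: 6 of 17 fell, 0 rose and 11 were not called (8 lower and 0 higher adjusted over the list alone). Their median was −1.09 over the list (camera adjusted p = 1.18e-06; adjusted p = 0.316 with an estimated correlation). Retnla, Ccl24 and the transcription factor gene Klf4 (−2.43 ± 0.21, 5.39-fold lower) kept their call without each array. Rnase2a fell 5.73-fold (−2.52 ± 0.33), but was not called without NCD2 or HFD3. Without NCD2, 3 of the 6 were called, and without NCD1 8 genes were lower and 1 higher. The arginase gene Arg1 was at −1.72 ± 0.40 (adjusted p = 0.0507).

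Pro-inflammatory genes did not move together. Of 22 cytokine and enzyme genes 1 rose, the interleukin-1 receptor antagonist Il1rn (2.09 ± 0.34), 2 fell, the cytokine signalling inhibitor Socs3 (−1.27 ± 0.13) and the chemokine Cxcl9 (−1.96 ± 0.45), and 19 were not called (1 higher and 2 lower adjusted over the list alone). Their median was −0.12 over the list (camera adjusted p = 0.206; adjusted p = 0.828 with an estimated correlation). Il1rn was not called without NCD2, HFD2 or HFD3, and Cxcl9 only in the full set and without NCD1. Tnf was at 0.88 ± 0.94 (adjusted p = 0.645), Il1b at 1.09 ± 1.03 (adjusted p = 0.595) and Il6 at −1.74 ± 1.04 (adjusted p = 0.371). The NCD arrays were far apart in Tnf, at 11.85, 10.58 and 7.78. Il1b was at 13.48, 13.33 and 10.64 on NCD1 to NCD3 and at 13.10, 12.22 and 15.39 on HFD1 to HFD3. The Il1b change ran from 0.17 to 1.76 over fits without 1 array. The list was called lower without NCD3 (median −0.64, adjusted p = 8.41e-05), with median centring (adjusted p = 0.0240) and with the covariate (median −1.07), and its median was 0.22 without NCD1 and −0.07 without NCD2. The genes called were 1 higher and 4 lower without NCD3 and 1 and 3 without NCD1.

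Among 29 chemokines and chemokine receptors, Cxcl14 (1.11 ± 0.10) and Ccr3 (1.13 ± 0.20) rose, Ccl12 (−1.87 ± 0.19), Ccl24 and Cxcl9 fell and 24 were not called (2 higher and 5 lower adjusted over the list alone). The list's median was −0.40 (camera adjusted p = 0.0465, adjusted p = 0.680 with an estimated correlation), and its call ended without NCD1 (median 0.01, adjusted p = 0.487), NCD2 (0.0551), HFD1 (0.0636) or HFD3 (0.0590). It also ended with genes of several lists left out (0.254), genes below the median level (0.0739) or the lowest 25% (0.0894) dropped, no trend (0.0512) and array weights (0.0526). The chemokine median was −0.66 without NCD3 and −0.94 with the endothelial covariate, and 2 genes were higher and 5 lower without NCD1. Ccr3 was not called without NCD2, HFD1, HFD2 or HFD3. Of 27 interferon-stimulated genes the guanylate-binding proteins Gbp3 (−1.49 ± 0.19), Gbp2 (−1.88 ± 0.24) and Gbp4 (−2.36 ± 0.43) and Ifit3 (−0.76 ± 0.16) fell, 0 rose and 23 were not called (2 higher and 5 lower adjusted over the list alone). The list was lower (median −0.29, camera adjusted p = 0.000623, adjusted p = 0.420 with an estimated correlation). That call was lost with the endothelial covariate (median −0.01, adjusted p = 0.147), and 1 of its genes was called without NCD2 or HFD3 and 0 without HFD2, while 9 were lower and 1 higher without NCD1 and 2 lower without NCD3. With the covariate Gbp2 was at −1.33, Gbp3 at −1.52 (adjusted p = 0.0537) and Gbp4 at −1.34 (adjusted p = 0.106). In MHC class II presentation the protease Ctss rose (0.65 ± 0.15, called only in the full set and without NCD1), 0 of 10 fell and 9 were not called (1 and 0 adjusted over the list alone). Their median was −0.21 over the list (camera adjusted p = 0.510; adjusted p = 0.854 with an estimated correlation). It was −0.01 without NCD1, −0.34 without NCD3 and −0.10 without HFD1, and the MHC list was called lower with the endothelial covariate (median −0.63, adjusted p = 1.86e-05).

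Immediate early and heat shock genes were lower. Of 22 measured, 12 fell, 0 rose and 10 were not called (16 lower and 0 higher adjusted over the list alone). Their median was −1.07 over the list (camera adjusted p = 9.91e-11; adjusted p = 0.348 with an estimated correlation). The AP-1 genes Fosb (−3.00 ± 0.33) and Jun (−2.07 ± 0.27), the antiproliferative gene Btg2 (−1.60 ± 0.19), Ier2 (−2.05 ± 0.27, not called without NCD2 or HFD3) and the transcription factor Klf2 (−1.80 ± 0.19) were among them. The mean deviation of the list was 0.93, 0.84 and 0.02 on NCD1 to NCD3 and −0.49, −0.47 and −0.83 on HFD1 to HFD3. The number called was 3 without NCD2, 6 without HFD1, 5 without HFD2, 4 without HFD3 and 16 without NCD3, and with the covariate 5 were called at a median of −1.45.

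Matrix remodelling genes went both ways, with 11 of 21 higher, 2 lower and 8 not called (12 higher and 3 lower adjusted over the list alone). Their median was 0.54 over the list (camera adjusted p = 0.000520; adjusted p = 0.319 with an estimated correlation). Beside Ctsk, the urokinase gene Plau rose by 2.64 ± 0.17, the collagenase Mmp13 by 2.24 ± 0.21 (4.71-fold) and Mmp27 by 1.27 ± 0.12, while the metalloproteinase inhibitor Timp3 fell by 2.90 and the gelatinase Mmp9 fell by 2.39, neither of them called without NCD2 or HFD2. The list call ended when genes below the median level were dropped (adjusted p = 0.0658), and the numbers higher were 5 without NCD2, 6 without HFD2 and 6 without HFD3. Among 35 macrophage transcription regulators Nr1h3 (liver X receptor alpha, 0.91 ± 0.13), Irf8 (1.24 ± 0.21) and Cebpa (1.04 ± 0.21) rose, Klf4, Klf2 and Id3 (−1.69 ± 0.34) fell and 29 were not called (11 higher and 8 lower adjusted over the list alone). Their median was −0.20 over the list (camera adjusted p = 0.388; adjusted p = 0.828 with an estimated correlation). Without NCD2, HFD2 or HFD3, Klf4 and Klf2 alone of these regulators were called, while 10 were higher and 5 lower without NCD1, at a median of −0.11.

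Stress programs were mixed. Hypoxia response genes Car9 (0.84 ± 0.09), Vegfa (0.78 ± 0.12) and Pgk1 (0.86 ± 0.15) rose, 0 of 21 fell and 18 were not called (7 higher and 5 lower adjusted over the list alone). Their median was 0.00 over the list (mean −0.06, camera adjusted p = 0.770; adjusted p = 0.828 with an estimated correlation). In the unfolded protein and integrated stress response, Psat1 rose (1.31 ± 0.22), Herpud1 fell (−0.93 ± 0.14) and 20 of 22 were not called (2 higher and 3 lower adjusted over the list alone). Their median was 0.02 over the list (mean −0.02, camera adjusted p = 0.910; adjusted p = 0.976 with an estimated correlation). Of 20 genes of oxidative stress and iron handling, Srxn1 (0.74 ± 0.10), Slc11a2 (0.77 ± 0.11), Steap3 (1.29 ± 0.21) and Txnrd1 (0.60 ± 0.13) rose, the ferroxidase Cp (−1.66 ± 0.19) and the iron exporter Slc40a1 (−0.84 ± 0.18) fell and 14 were not called (6 higher and 3 lower adjusted over the list alone). Their median was 0.12 over the list (mean −0.04, camera adjusted p = 0.379; adjusted p = 0.705 with an estimated correlation). In these 3 stress lists, Car9 and Cp alone were called without NCD2, HFD2 or HFD3. Without NCD1, 5 hypoxia genes were higher and 4 lower, 3 and 2 of the unfolded protein response and 6 and 3 of oxidative stress. The medians ran from −0.04 to 0.03, −0.03 to 0.03 and 0.02 (NCD3) to 0.17 over fits without 1 array, and the last was −0.00 with the covariate.

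**Figure D3:**
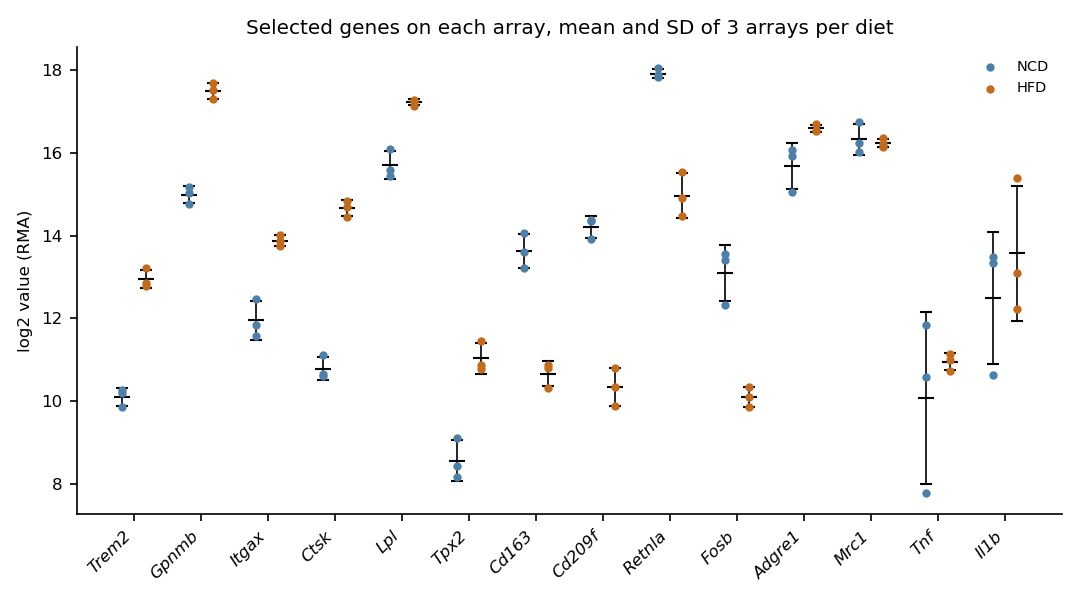
Log2 expression (vertical axis) of 14 genes on the 3 NCD and 3 HFD arrays, each point 1 array, with the mean and SD of each diet as bars. Trem2 (2.85) and Cd163 (−2.97) were called, while Adgre1 (0.91), Mrc1 (−0.09), Tnf (0.88) and Il1b (1.09) were not.

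Among macrophage identity genes, the Fc receptor Fcgr1 (1.43 ± 0.21) and Cd68 (1.20 ± 0.22) rose, the efferocytosis receptor Mertk fell (−0.49 ± 0.10) and 12 of 15 were not called (3 higher and 1 lower adjusted over the list alone). Their median was 0.11 over the list (camera adjusted p = 0.346; adjusted p = 0.828 with an estimated correlation). The mean deviation of the list was 0.12, 0.08 and −0.58 on NCD1 to NCD3 and 0.05, 0.18 and 0.15 on HFD1 to HFD3. The identity median was 0.28 without NCD1, −0.12 without NCD3, 0.02 without HFD2 and −0.19 with the endothelial covariate. Of the 3 identity genes called, 0 were called without HFD2 or HFD3 and 1 without NCD2 or HFD1. Of the 10 monocyte markers Ace fell (−2.27 ± 0.40, not called without NCD2, HFD2 or HFD3), 0 rose and 9 were not called, among them Ly6c2 (−1.71 ± 0.52). The monocyte list was lower (1 gene lower adjusted over the list alone). Their median was −0.54 over the list (camera adjusted p = 0.00345; adjusted p = 0.316 with an estimated correlation). It was −0.30 without NCD1 (3 genes lower), −0.93 without NCD3 and −1.21 with the endothelial covariate, with which Ly6c2 was at −0.31 and Ace at −1.44 (adjusted p = 0.153). Large peritoneal macrophage markers had Icam2 (−1.20 ± 0.17) and Gata6 (−1.24 ± 0.28) lower, 0 higher and 7 of 9 not called (3 lower adjusted over the list alone). Their median was −0.73 over the list (camera adjusted p = 0.000327; adjusted p = 0.464 with an estimated correlation). Without NCD2 or without HFD2, 0 of these 9 genes were called, while without NCD3, whose mean deviation of −0.32 lay among the HFD arrays, 5 were called at a median of −1.24. The peritoneal median was −0.53 without NCD1. With the covariate it was −1.34, but 0 of the 9 genes were called, with Icam2 at −0.89 and Gata6 at −1.49. Dendritic cell markers had Cd209a (−2.99 ± 0.31) and Siglech (−1.32 ± 0.15) lower, 0 higher and 11 of 13 not called (1 higher and 3 lower adjusted over the list alone). Their median was −0.37 over the list (camera adjusted p = 0.0285; adjusted p = 0.348 with an estimated correlation). The dendritic cell call ended without NCD1 (median −0.05, 5 genes lower and 1 higher, adjusted p = 0.0851) and without HFD3 (adjusted p = 0.0792), with array weights (0.0637) and with genes of several lists left out (0.0661). The dendritic median was −0.24 without NCD3 and −0.12 with the covariate.

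Markers of stromal cells, which the magnetic selection should have removed, differed between the diets and in opposite directions. Mesothelial markers, genes of the serosal lining, were lower: 10 of 11 fell, 0 rose and 1 was not called (11 lower adjusted over the list alone). Their median was −1.76 over the list (camera adjusted p = 1.96e-13; adjusted p = 0.316 with an estimated correlation). The uroplakins Upk1b (−3.34 ± 0.29, 10.1-fold lower) and Upk3b (−3.30 ± 0.33) and the keratins Krt19 (−1.12 ± 0.08) and Krt8 (−1.03 ± 0.08) were called without each array, and the number of genes called was 5 without HFD2 and 6 without HFD3. Fibroblast and adipose progenitor markers were higher: 8 of 16 rose, 0 fell and 8 were not called (8 higher and 2 lower adjusted over the list alone). Their median was 0.48 over the list (camera adjusted p = 0.000843; adjusted p = 0.348 with an estimated correlation). The actin-severing gelsolin Gsn rose by 1.08 ± 0.10, the proteoglycan Lum by 2.55 ± 0.25 (5.86-fold), and the collagen gene Col1a1 by 1.95 ± 0.24. Dcn was at −0.88 (adjusted p = 0.126). The number of fibroblast markers called was 4 without NCD2, 3 without HFD2 and 5 without HFD3, all higher, and without NCD1 8 were higher and 2 lower.

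Endothelial markers had 0 of 12 genes called (0 adjusted over the list alone), while the list as a whole was lower (median −1.85, camera adjusted p = 1.97e-05, adjusted p = 0.510 with an estimated correlation). Vwf was at −2.74 ± 0.74, Emcn at −2.50 ± 0.74, Tek at −2.27 ± 0.70 and Pecam1 at −1.77 ± 0.59. The arrays of a diet were far apart: the mean deviation was −0.53, 1.48 and 1.93 on NCD1 to NCD3 and −0.01, −1.43 and −1.43 on HFD1 to HFD3, and without NCD1 all 12 genes were called lower. Smooth muscle and pericyte markers, a list added after the values were seen, had 9 of 16 genes lower, 0 higher and 7 not called (12 lower adjusted over the list alone; median −1.99). Its set tests, outside the adjustment over lists, gave a camera p of 1.70e-10, a p of 0.140 with an estimated correlation and a fry p of 0.0257, and they are not independent of the values that led to the list. Their mean deviation was 0.22, 1.13 and 2.12 on NCD1 to NCD3 and −0.73, −1.28 and −1.47 on HFD1 to HFD3.

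**Figure D4:**
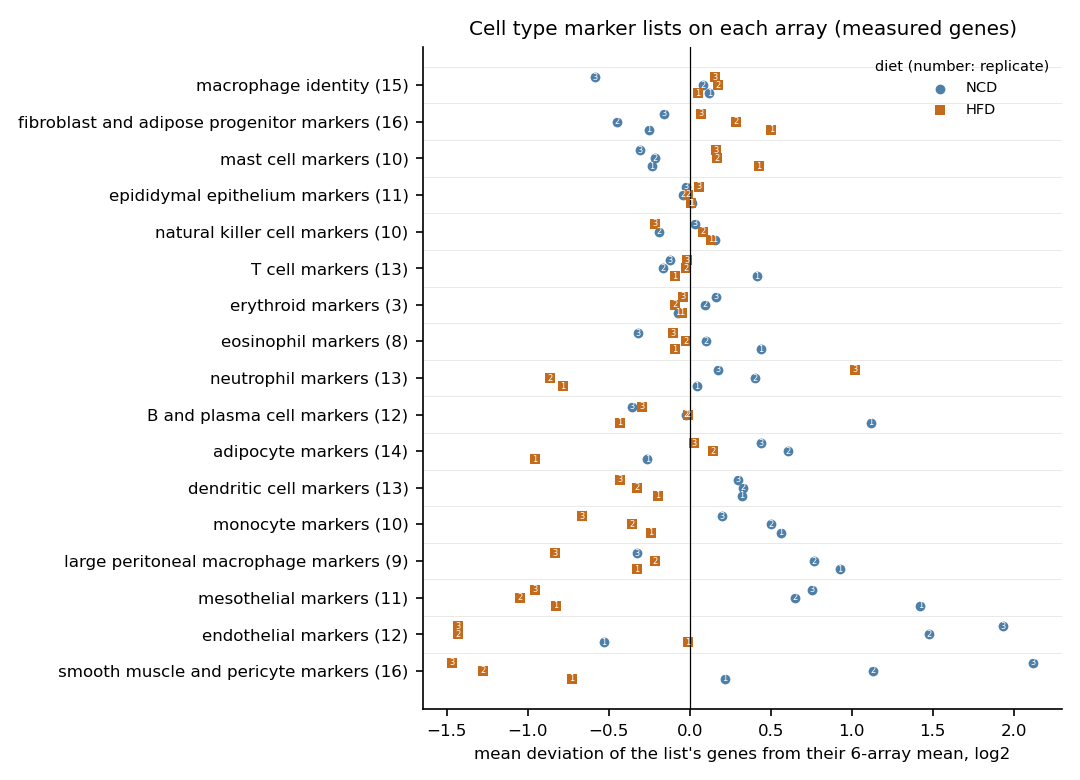
Mean log2 deviation of each cell type list from its 6-array mean (horizontal axis) on each NCD and HFD array, 1 row per list with its number of measured genes and 1 numbered point per array. Mesothelial values were 1.42, 0.65 and 0.76 on the NCD arrays and −0.83, −1.05 and −0.96 on the HFD arrays.

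Mast cell markers had 4 of 10 genes higher, the proteases Mcpt4 (1.66 ± 0.20), Tpsb2 (0.89 ± 0.15), Cma1 (0.92 ± 0.15) and Cpa3 (2.66 ± 0.46), 0 lower and 6 not called (4 higher and 1 lower adjusted over the list alone; median 0.10, mean 0.51, camera adjusted p = 0.0309, adjusted p = 0.348 with an estimated correlation); the call ended without NCD1 (adjusted p = 0.176), without HFD1 (0.0539), with median centring (0.0743), with genes below the median level (0.567) or the lowest 25% (0.0661) dropped and with array weights (0.0623), and 0 of its genes were called without NCD2. The mast cell median was 0.31 with the covariate, with 1 gene called. T cell markers had Il7r higher (2.79 ± 0.36, 6.91-fold), Cd8b1 lower (−0.43 ± 0.08) and 11 of 13 not called (1 higher and 2 lower adjusted over the list alone). The T cell list was lower (median −0.18, camera adjusted p = 0.0465, adjusted p = 0.680 with an estimated correlation). That call was lost without NCD1 (median −0.06, adjusted p = 0.414), HFD1 (0.0539), HFD2 (0.0547) or HFD3 (0.0756), with quantile normalization again (0.0722), the lowest 25% dropped (0.0853), no trend (0.0512) or array weights (0.173), and Il7r was not called without HFD2 or HFD3. The T cell median was −0.48 with the covariate. Adipocyte markers had 0 of 14 genes called (2 lower adjusted over the list alone). Their median was −0.68 over the list (camera adjusted p = 0.0212; adjusted p = 0.594 with an estimated correlation). Slc2a4 was at −0.87 ± 0.21, and the adipocyte call ended without NCD2 (adjusted p = 0.0551), NCD3 (0.0566) or HFD1 (0.266). The adipocyte median was −0.29 without HFD1, with 2 genes called higher and 0 lower, and −0.89 without NCD1, with 4 lower.

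Neutrophil markers had Mmp9 lower (not called without NCD2, NCD3, HFD1 or HFD2), 0 higher and 12 of 13 not called (2 lower adjusted over the list alone; median −0.08, camera adjusted p = 0.0736, adjusted p = 0.675 with an estimated correlation); without HFD3 the median was −0.80 (adjusted p = 1.22e-06) and with median centring it was 0.01; the neutrophil list was called in both (adjusted p = 0.0236 with centring) and with the replicate block (0.0345). Its median was −0.28 without NCD1, −0.23 without NCD3, −0.04 without HFD1, 0.00 without HFD2 and −0.38 with the covariate. The mean deviation of the neutrophil list was 0.04, 0.40 and 0.18 on NCD1 to NCD3 and −0.78, −0.86 and 1.02 on HFD1 to HFD3. HFD3 was also the array with the highest Il1b value (15.39). Eosinophil markers had Ccr3 higher and 7 of 8 not called (1 higher adjusted over the list alone). Their median was −0.16 over the list (camera adjusted p = 0.234; adjusted p = 0.705 with an estimated correlation), −0.07 without NCD1, −0.27 without NCD3 and −0.40 with the covariate. B and plasma cell markers had 0 of 12 called (0 adjusted over the list alone). Their median was −0.51 over the list (camera adjusted p = 0.0855; adjusted p = 0.708 with an estimated correlation). Jchain was at −2.33 ± 0.68, and the B and plasma cell list was called lower without NCD2 (adjusted p = 0.0332), NCD3 (0.00509) or HFD2 (0.0351), with median centring (0.0132) and with the covariate (median −1.36, adjusted p = 3.91e-09). Its mean deviation was 1.12 on NCD1, where Jchain was at 10.56 against 7.83 and 8.17 on NCD2 and NCD3, and without NCD1 the median was −0.05 (adjusted p = 0.669). Natural killer cell markers had 0 of 10 called (median 0.05, camera adjusted p = 0.996, adjusted p = 0.999 with an estimated correlation) and epididymal epithelium markers 0 of 11 (median 0.03, camera adjusted p = 0.763, adjusted p = 0.849 with an estimated correlation), both with 0 adjusted over the list alone. Over fits without 1 array the medians ran from −0.05 to 0.11 and from 0.00 to 0.04. Of the erythroid markers 3 were measured, too few for the set test, and 0 were called (Alas2 −0.28 ± 0.19).

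Of the 35 lists tested, 9 were called higher and 12 lower with the preset correlation, 0 with an estimated correlation (5 lists at an unadjusted p under 0.05) and 10 higher and 4 lower with fry, by the sign of the median. The lists gained with fry were hypoxia response (adjusted p = 0.00698), lipid uptake and glycolysis (0.0280 each). Those lost with fry were oxidative phosphorylation, fatty acid oxidation, chemokines (0.592), interferon-stimulated genes, monocytes, large peritoneal macrophages, dendritic cells, T cells, adipocytes and endothelium. The background filter ended the calls of the fatty acid oxidation (0.0568), chemokine (0.0853), mast cell (0.126) and T cell (0.591) lists. With the endothelial covariate 11 were called higher and 14 lower. Gained were the lists of lipid uptake (adjusted p = 0.000377), glycolysis (0.0317), MHC class II, B and plasma cells, pro-inflammatory genes (1.34e-05), eosinophils (0.0119) and transcription regulators (0.0172), and lost were those of adipocytes (0.242), interferon-stimulated genes and endothelium. An estimated correlation draws on 6 arrays, and the NCD arrays differed among themselves by more than the HFD arrays.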

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

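All tests of explanations in this part were chosen after the results they address were seen.

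Transcript clusters without a gene symbol lie outside the gene comparison, and of 33206 such clusters 378 were higher and 285 lower after HFD at an adjusted p below 0.05, a smaller share (2.00%) than of the 30604 clusters with 1 symbol, of which 984 were higher and 545 lower. The largest rises were in TC0100003023.mm.1 (4.14) and TC0100003022.mm.1 (4.01), whose identifiers follow that of the Zranb3 cluster directly, and the largest falls in TC1000000022.mm.1 (−3.37) and TC0900001806.mm.1 (−3.26). The NCD means of the rising clusters (6.16 and 6.19) and the HFD mean of TC0900001806.mm.1 (5.89) lay below the background level of 6.23. The size of these changes is therefore uncertain.

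Mesothelial and smooth muscle genes were lower after HFD, and endothelial genes had a median of −1.85 with 0 of 12 called (adjusted p = 0.510 with an estimated correlation), although the selection for macrophages should remove those cells; their markers of highest array signal averaged 16.05 in NCD and 14.56 in HFD arrays (Cdh5), 15.44 and 10.78 (Acta2) and 12.07 and 9.13 (Efemp1). Cells outside the macrophage lineage may have been carried over in larger shares in the NCD pools. The fibroblast list moved against the mesothelial list by 2.46 log2 (SD between pools 0.19 and 0.31). This argues against a carry-over that raised every other cell type alike. It does not exclude one that differed between cell types. Of the 16 fibroblast markers 12 had a positive and 4 a negative sign, the latter including Dcn. For the endothelial genes, variation between pools of the same diet remains a candidate explanation, since the lowest NCD array lay below the highest HFD array (gap −0.52). For the mesothelial genes the lowest NCD array lay above the highest HFD array by 1.48 (SD between pools 0.31), and for the smooth muscle genes by 0.95 (SD 0.73). The mesothelial gap exceeded the SD of the arrays of either diet (0.42 in NCD and 0.11 in HFD). The smooth muscle gap exceeded the SD pooled over both diets, but it was no larger than the SD of the NCD arrays alone (0.95). These patterns were picked because they were lower on the same arrays, so the gaps are no independent test. Variation between pools was not excluded. A biological change in the tissue's mesothelial and vessel cells after HFD stays open and untested.

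Cell cycle genes rose together. Purer macrophages in the HFD pools would raise macrophage identity genes by a like amount. The median of the cell cycle list lay 1.62 above that of the identity list (interquartile ranges 1.08 and 0.71). The identity median was −0.12 to 0.28 over fits without 1 array. This argues against purity as the whole cause, but the ranges are spreads across genes and not between pools. Within the identity list Cd68 (1.20) and Fcgr1 (1.43) rose, Mertk (−0.49) fell and 12 of 15 genes were not called. With the endothelial score as a covariate the median was still 1.34, which argues against less endothelial RNA as the whole cause, although 7 genes were called in place of 29, for a cause that was not tested. Dividing cells of another type may contribute, since 2 other cell type lists were called higher (fibroblasts and mast cells; adjusted p = 0.348 for both with an estimated correlation, the mast cell call lost without NCD1 or HFD1, among others); their markers of highest signal, Dcn (13.05 in NCD, 12.16 in HFD) and Hdc (8.60, 8.36), were not called. It cannot be told apart from dividing macrophages here. More dividing macrophages after HFD is a biological hypothesis that these arrays leave open.

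Immediate early and heat shock genes were lower after HFD. More endothelial RNA in the NCD pools as the cause is argued against by the fit with the endothelial covariate, in which the median was −1.45 against −1.07 without it. A difference in handling between the diets may raise these genes, since NCD pools took 20 mice and HFD pools 10; the lowest NCD array lay above the highest HFD array by 0.49, but pool size and diet coincide, so the 2 cannot be told apart. An effect of the diet on these genes stays open and untested.

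The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05: the real split called 2359 genes, the highest of the others 0, so 1 split of the 10 gave as many.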

How the results depend on the processing

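The filter at the antigenomic background level and the endothelial covariate were chosen after the data were seen. Among the genes called in the main fit, 0 changed sign in the alternatives compared gene by gene, except 1 with averaged probe sets, whether or not the alternative called them. The level filters, no trend, robust shrinkage, the F test and the block keep the log2 change of each gene, so no sign could change there. Genes higher numbered 1496 to 1881 (main value 1494) and genes lower 756 to 1026 (865) with quantile normalization again, the dim gene filters, averaged probe sets, no trend and robust shrinkage. The fit of all transcript clusters counted clusters and not genes, 1413 higher and 865 lower. Among its clusters with 1 symbol, 984 were higher and 545 lower. Higher counts moved to 2573 with median centring, 2345 with array weights, 75 with the F test without shrinkage, 90 with the replicate block and 310 with the endothelial covariate; lower counts to 1937 with weights, 39 with the F test, 54 with the block and 363 with the covariate. At 2-fold or more, the higher count moved to 45, 89 and 265 with the F test, the block and the covariate, and the lower count to 840, 16 and 51 with weights, the F test and the block. Leaving out 1 array each gave 316 to 2399 genes higher (264 to 823 at 2-fold), 124 to 2314 lower (98 to 1219 at 2-fold), 7 to 10 lists higher and 9 to 13 lower. The F test without shrinkage lacked the prior degrees of freedom. The block, the covariate and the fits without 1 array left fewer residual degrees of freedom than the main fit. How far this moved their counts was not tested, and for the other counts the cause was not tested. Of the lists, 0 were higher and 0 lower with an estimated correlation, and 4 were lower with fry. The endothelial list reversed to 0.0680 with its own score as covariate, which removes it by construction. Robust shrinkage and the F test gave no list value. At an unadjusted p the F test gave 632 genes higher and 624 lower by 2-fold or more.

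The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at −0.46, −0.12 and −0.15 across genes, and the best partner had another number each time. Of the 158 named genes, calls lost numbered 73 with the block and 88 with the F test. In each alternative, 0 named genes called there or in the main fit changed sign. For the alternatives that keep the log2 change of each gene, this could not come out otherwise. Genes called in neither fit could change sign. With the endothelial covariate, Tnf was at −0.86 against 0.88 and Il1b at −0.32 against 1.09. Signal over background limits the dim genes: 14395 genes lay below the background level, and 263 of those called were among them.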

Other observations

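The gene families in this part were picked and tested after the data were seen, by camera over 611 families of symbols with a common stem; each adjusted p given was lost with an estimated correlation (adjusted p = 0.946).

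All 7 measured genes of the Cd209 family of C-type lectins fell, with a median of −3.40 (−3.31 after median centring, camera adjusted p = 2.80e-10), and 6 or 7 of them were called without each array in turn. All 7 guanylate-binding protein genes fell (median −1.91, −1.82 after median centring, camera adjusted p = 5.27e-07), among them Gbp7 (−2.04), Gbp8 (−1.70), Gbp9 (−1.94) and Gbp11 (−1.91); the number called was 2 without NCD2, 1 without HFD2 and 2 without HFD3. With the endothelial covariate Gbp2 was at −1.33 in place of −1.88 and Gbp4 at −1.34 in place of −2.36 (adjusted p = 0.106), and in 6 of the 7 NCD1 was the lowest NCD array and HFD1 the highest HFD array, as in the endothelial list. In both families members share sequence, so the counts are not of independent genes. Of 17 Klf transcription factor genes 7 fell and 0 rose (median −0.55, camera adjusted p = 0.000905), with 3 called without NCD2, 3 without HFD1, 2 without HFD2 and 2 without HFD3. Of 11 annexin genes, which bind membranes in a calcium-dependent way, 5 rose and 0 fell (median 0.42, camera adjusted p = 0.0181), among them Anxa1 (1.33), Anxa2 (1.16), Anxa4 (1.22) and Anxa5 (0.86), with 3 called without NCD2, HFD2 or HFD3. Of 7 insulin-like growth factor binding protein genes Igfbp5 (−3.47), Igfbp4 (−1.79) and Igfbp6 (−1.40) fell and 0 rose (median −1.57, camera adjusted p = 0.00501), with 5 called without NCD1 and 2 without NCD2, HFD1, HFD2 or HFD3.

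Immunoglobulin variable segments were lower as a group: of 113 heavy chain segments 9 fell and 0 rose (median −1.44, camera adjusted p = 6.05e-19), and of 86 kappa segments 12 fell and 0 rose (median −1.02, camera adjusted p = 1.93e-16). The 9 heavy chain calls are near the 7.83% called over all genes. Without NCD1 the medians were −0.75 and −0.62, but 36 heavy chain and 28 kappa segments were called. The numbers called were 2 and 3 without NCD2, 14 and 27 without NCD3, 1 and 1 without HFD1, 2 and 4 without HFD2 and 0 and 1 without HFD3. The signs of all families given here were the same after quantile normalization again and after median centring.

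NCD1 and NCD3 lay further from the mean of their diet (root mean square deviation 0.285 and 0.256 over genes) than NCD2 (0.168) and the HFD arrays (0.144 to 0.166). The first principal component held 66.3% of the variance and the second 18.4%.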
